A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

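Total RNA from 4 yeast cultures was measured on the Affymetrix Yeast Genome 2.0 array. Per the labels, the strain was BY4741 (mating type a), grown in synthetic medium without leucine to mid-log phase. It carried either the multicopy LEU2 plasmid p425-GPD with an RNase H1 insert (2 arrays) or the same plasmid without insert (2 arrays). RNA was amplified in vitro before hybridisation. The deposited values are signals on a linear intensity scale, 1 per probe set and array, which the authors made with Affymetrix Expression Console and the MAS5 algorithm, per the submitters' processing notes. The scaling target of MAS5 is not given in the sources used here, and the table held 0 other columns per sample. Signal sums per array lay between 6889760 and 7097920. For arrays like these, the number of arrays limits the precision.

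Of the 10928 probe sets in the table, 7245 were listed in the array annotation. These were 5498 with exactly 1 S. cerevisiae gene, 1746 of S. pombe, which shares the array, and 1 with several genes. A further 3470 were unlisted, and 213 were control or reporter probe sets. Gene names followed the R64 annotation of the yeast genome, which updated 12 symbols and gave chromosomes and neighbours. S. pombe probe sets served as the background: the mean log2 signal of a tested probe set had to lie above the 75th percentile of theirs, a signal of 2.13. This left out 28 dim probe sets and kept 5470 probe sets of 5425 genes.

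The samples were grouped by plasmid, as the labels give it. Per the labels the replicates were biological; whether equal numbers in the 2 groups share a day or a batch is not stated, so the arrays were treated as unpaired, and pairing was tried as an alternative. The log2 signals were compared as arrays labelled RNase H1 minus arrays labelled empty vector with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All tests were two-sided, except the permutation test of neighbouring genes, which counted only random sets with at least as many pairs. An exact two-sided permutation test of 2 arrays against 2 cannot go below p = 0.333, so single genes have the adjusted p of the limma model only. The same steps were tested on simulated data in 20 runs with 200 changed genes of 5470. Each gene had the same spread in both groups, pooled from these arrays, and genes varied independently. The steps recovered 5% of the genes changed by 0.58 on the log2 scale and 38.7% of those changed by 1. Of those changed by 2 and by 4, they recovered 63.2% and 88.9%. Of the genes called, 3.78% were false. In the real arrays the median SD was 0.236 in those labelled RNase H1 and 0.0756 in the controls. Genes were also correlated there, at an estimated 0.98 in the induced stress response list. The shares may therefore not carry over.

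Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 35 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also takes its degrees of freedom from the arrays, 2 here, so few lists can pass whatever their correlation. The lists were RNase H and R-loop factors, the iron, zinc, copper and phosphate regulons, sulphur genes, amino acid biosynthesis, the leucine pathway, ribosomal proteins, ribosome biogenesis, the induced stress response, heat shock chaperones, the unfolded protein response, DNA damage genes and histones. They also held a-specific, alpha-specific, pheromone and meiosis genes, the tricarboxylic acid cycle, the nuclear respiratory chain, mitochondrially encoded genes, gluconeogenesis, galactose genes, hexose transporters, glycolysis, ergosterol, thiamine and purine synthesis, and the proteasome. The last were drug resistance genes (Pdr1/Pdr3), Ty elements, subtelomeric helicases with COS genes, seripauperins, flocculins, genes with textbook non-coding transcription, and the strain markers.

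The lists, the test, the threshold, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule names the 12 largest rises and the 12 largest falls past the threshold whose arrays did not overlap. It also takes up to 4 members of each list with the smallest p, and always RNH1, RNH201, RNH202, RNH203, LEU2, URA3, HIS3 and MET17. Examples in the text are drawn from these. The alternative settings were quantile, median and cyclic loess scaling, no dim filter or one at the 95th percentile, pseudocounts of 16 and 64, no intensity trend, robust eBayes, a replicate block, each array left out, an adjusted p under 0.10, fold minima, and the other list tests. A mean signal above 100 and a crossed block were added after seeing the data. The signals of unlisted, S. pombe and reporter probe sets were left out of the comparison because they name no S. cerevisiae gene, and are described apart.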

Results

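Transcript levels were measured in 4 cultures of budding yeast: 2 labelled as carrying an RNase H1 plasmid and 2 labelled as carrying the empty vector. RNase H1 degrades the RNA strand of RNA-DNA hybrids, and the comparison addresses which transcripts differ when the plasmid carries its gene. Signal sums were 7097920 and 7074860 in the 2 control arrays and 6889760 and 6972050 in the 2 arrays labelled RNase H1. The median signal of S. cerevisiae probe sets was 570, against 1.11 for S. pombe probe sets. The ratio of 3' to 5' actin signal, a measure of RNA quality and amplification, was 1.34 in both control arrays and 1.68 and 1.48 in the arrays labelled RNase H1.

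RNH1, the yeast gene of RNase H1, had signals of 320 and 292 in the control arrays and 303 and 307 in the arrays labelled RNase H1. Its log2 fold change was −0.00444 ± 0.18 (SE, n = 2 against 2, adjusted p = 0.990), so its probe set did not set the groups apart. The labels do not say from which species the insert came. The RNH1 probe set checks the labels only for a yeast insert, and directions below are given between arrays as labelled.

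The largest rise was that of NCA3 (YJL116C), a cell wall and mitochondrial gene of the SUN family, which was 74.1-fold higher in the arrays labelled RNase H1 (log2 6.21 ± 0.21 SE, n = 2 against 2). In the iron regulon 13 of 29 genes rose, among them TIS11 (YLR136C), an RNA-binding protein that removes transcripts of iron-using proteins, at 42.8-fold (5.42 ± 0.29). The phosphate transporter gene PHO89 (YBR296C) was 38.7-fold higher (5.27 ± 0.32), and RSB1 (YOR049C), which moves sphingoid bases across the plasma membrane, 34.6-fold (5.11 ± 0.23). Among mating genes, PRM1 (YNL279W), a membrane fusion gene, was 8.16-fold lower (−3.03 ± 0.39), and FUS1 (YCL027W), a cell fusion gene, 6.86-fold lower (−2.78 ± 0.24). With a pseudocount of 64, PRM1 was at −1.28 and not past the threshold (adjusted p = 0.0683; 0.0519 with a pseudocount of 16), and NCA3 was at 4.03. In the limma model, 81 of 5470 probe sets passed the threshold (1.48%), 62 higher and 19 lower, and at an unadjusted p under 0.05 there were 600 higher and 697 lower. The median change was 3.32-fold among those that rose and 3.25-fold among those that fell. Without an intensity trend in limma, 7 probe sets passed as higher and 0 as lower. PHO89, BAR1, PDR5 and FUS1 were then among those not past the threshold (adjusted p between 0.0546 and 0.0722). Others lay farther from it, such as STE2 (adjusted p = 0.113), PHO84 (0.146) and CUP1-1 (0.237). Of the 55 called genes named here, 48 were lost in this setting. The 2 groups did not overlap in any of the 81. Passing the test on these same 4 arrays nearly ensures this, so it is no separate support. For a gene not so selected, chance gives such a separation with a probability of 0.333. The arrays labelled RNase H1 differed from each other more than the controls did, with 1550 against 182 probe sets over 1.5-fold apart. A fit without 1 array of the pair labelled RNase H1 takes its spread from the controls alone. Passing in such a fit, here and below, is no sign of robustness. Without array 1 of that pair 1184 probe sets passed as higher and 1604 as lower, without array 2 932 and 829, without control array 1 54 and 10, and without control array 2 57 and 10.

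**Figure D1:**
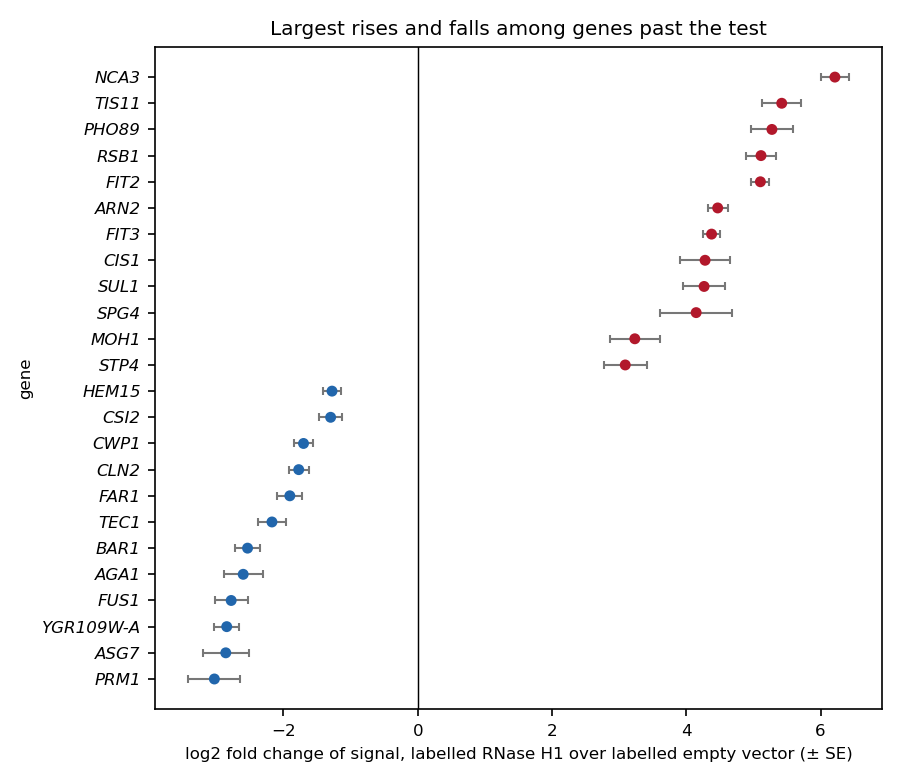
Log2 fold change of signal (x axis, arrays labelled RNase H1 over arrays labelled empty vector) of the 12 largest rises and 12 largest falls past the test (y axis), as points with bars of 1 SE. Rises reach 6.21 (NCA3) and falls reach −3.03 (PRM1).

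Among the 29 genes of the iron regulon, 13 rose and 0 fell over all genes, and 24 rose when adjusted over the list alone. Genes of iron metabolism are, as recalled, among those the study discussed from these samples, so the list is not independent evidence of its direction. FIT2, a cell wall protein that retains iron carriers, rose from a signal of 196 to 6724 (34.4-fold, log2 5.10 ± 0.13, adjusted p = 0.00150), and its neighbour FIT3 rose 20.8-fold (4.38 ± 0.12). ARN2, a transporter of iron-siderophore complexes, rose 22.1-fold (4.47 ± 0.15). All 29 log2 fold changes lay above 0, with a median of 1.43, and the list passed the list test (adjusted p = 1.78e-19 with the preset correlation, adjusted p = 0.42 with an estimated correlation). The list's median difference from the controls was 1.55 in array 1 and 1.58 in array 2 labelled RNase H1, which had the higher actin 3' to 5' ratios. Without array 1 of that pair 24 members passed, and without array 2 26. HEM15, the last enzyme of haem synthesis, which puts iron into the ring, was 2.42-fold lower (−1.28 ± 0.13, adjusted p = 0.0319). It was not past the threshold without either control array (adjusted p between 0.131 and 0.221). In the zinc regulon, 1 of 13 members was higher over all genes and 1 when adjusted over the list alone: FET4, a low-affinity iron transporter, at 3.49-fold (1.80 ± 0.23). FET4 did not pass without control array 1 (adjusted p = 0.120) or after median scaling (adjusted p = 0.0530). The zinc list did not pass the list test (adjusted p = 0.139) but passed without control array 1 (adjusted p = 0.0186) and without control array 2 (adjusted p = 3.05e-04), and its median of 0.47 was 0.10 without array 2 labelled RNase H1.

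**Figure D2:**
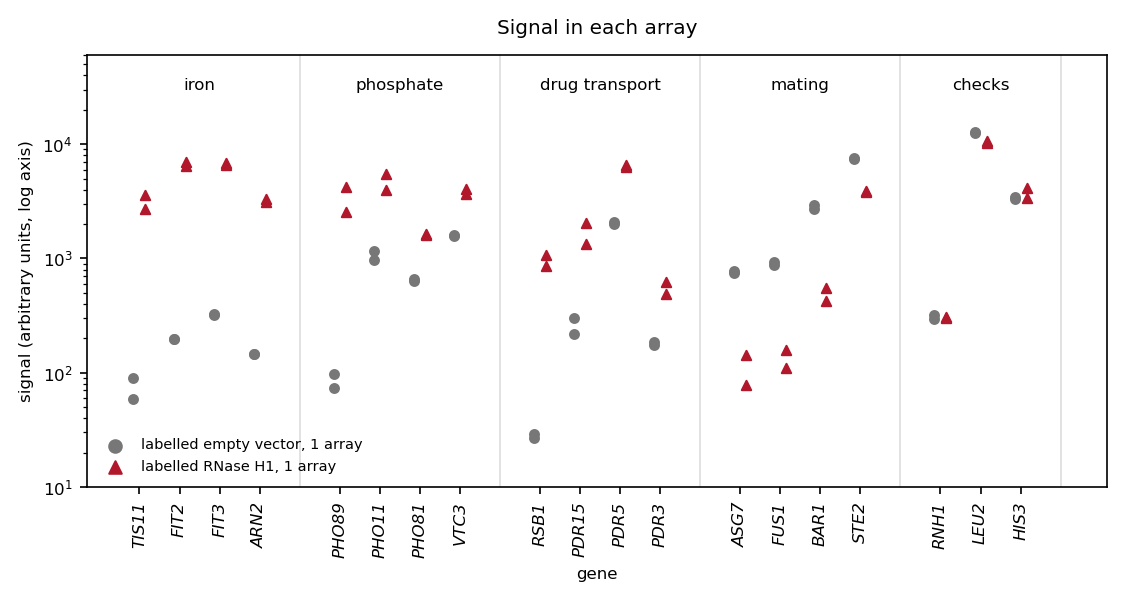
Signal in each of the 4 arrays (y axis, arbitrary units, log axis) for genes of 4 groups and for 3 genes that check the labels (x axis); circles are arrays labelled empty vector and triangles arrays labelled RNase H1. FIT2 lies at 196 on average in the controls and at 6724 in the others, while RNH1 lies between 292 and 320 in all 4 arrays.

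Of 17 phosphate genes under the activator Pho4, 7 were higher and 0 lower over all genes, and 15 were higher when adjusted over the list alone. Besides PHO89, these included PHO11, a secreted acid phosphatase whose probe set is shared with its close relative PHO12, at 4.43-fold (log2 2.15 ± 0.19), and VTC3, a subunit of the polyphosphate polymerase, at 2.42-fold (1.28 ± 0.11). PHO81, an inhibitor of the cyclin-dependent kinase that represses the pathway, was 2.51-fold higher (1.33 ± 0.14), and the high-affinity transporter gene PHO84 1.76-fold (0.82 ± 0.11). The list's median was 1.28, and all 17 members lay above 0 (adjusted p = 2.25e-13 with the preset correlation, adjusted p = 0.43 with an estimated correlation). PHO81 did not pass without either control array (adjusted p between 0.127 and 0.160), nor PHO84 without control array 2 (adjusted p = 0.0629) or after median scaling (adjusted p = 0.0913). Without array 1 labelled RNase H1 16 members passed, and without array 2 15.

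Of 13 drug resistance genes controlled by Pdr1 and Pdr3, 4 were higher and 0 lower over all genes, and 10 were higher when adjusted over the list alone. These 4 were RSB1, the drug efflux pumps PDR15 at 6.46-fold (log2 2.69 ± 0.29) and PDR5 at 3.18-fold (1.67 ± 0.08, adjusted p = 0.00772), and the activator gene PDR3 at 3.06-fold (1.61 ± 0.21). The list's median was 1.16 (adjusted p = 1.58e-08 with the preset correlation, adjusted p = 0.42 with an estimated correlation). Outside the list, CIS1, a gene induced through Pdr3 when import into mitochondria stalls, rose 19.4-fold (4.28 ± 0.37, adjusted p = 0.0242), and its log2 fold change was 2.44 with a pseudocount of 64. PDR3 did not pass without either control array (adjusted p between 0.240 and 0.258). Without array 1 labelled RNase H1 11 members passed, and without array 2 10.

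Of 24 pheromone response genes, 5 were lower and 0 higher over all genes, and 16 were lower and 2 higher when adjusted over the list alone. Of 7 a-specific genes, 3 were lower and 0 higher over all genes, and all 7 were lower when adjusted over the list alone. ASG7, an a-specific regulator of the pheromone pathway that stands in both lists, was 7.26-fold lower (log2 −2.86 ± 0.34, adjusted p = 0.0428). AGA1, the cell surface anchor of a-agglutinin, was 6.06-fold lower (−2.60 ± 0.29). BAR1, the secreted protease that degrades alpha-factor, fell from 2820 to 491 (5.80-fold lower, −2.54 ± 0.18), and STE2, the alpha-factor receptor gene, from 7439 to 3878 (1.92-fold lower, −0.94 ± 0.06). The pheromone list had a median of −0.82 (adjusted p = 3.41e-08 with the preset correlation, adjusted p = 0.43 with an estimated correlation) and the a-specific list one of −0.94 (adjusted p = 7.45e-07 with the preset correlation, adjusted p = 0.43 with an estimated correlation). FAR1, the inhibitor that arrests cells in G1 on pheromone, was 3.75-fold lower (−1.91 ± 0.19), and the G1 cyclin gene CLN2 3.42-fold lower (−1.77 ± 0.15). TEC1, an activator of filamentous growth genes, was 4.51-fold lower (−2.17 ± 0.21), and YGR109W-A, which encodes the Gag protein of the retrotransposon Ty3 and whose probe set is not specific to 1 transcript, 7.19-fold lower (−2.85 ± 0.19). FAR1, CLN2 and PRM1 did not pass without either control array (adjusted p between 0.0758 and 0.272). Pheromone genes past the threshold numbered 3 without control array 1, 3 without control array 2, 21 without array 1 labelled RNase H1 and 17 without array 2, and a-specific genes 7 without either of the latter.

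The alpha-specific list of 4 had a median of −0.17 but a mean of 0.21, and its test pointed up (adjusted p = 0.793). MF(ALPHA)1, the main alpha-factor gene, did not pass (log2 −0.24 ± 0.63, adjusted p = 0.84). The a-factor receptor gene STE3 had a log2 fold change of 1.45 ± 0.40 (adjusted p = 0.13). It was 1.02 without array 1 and 1.88 without array 2 labelled RNase H1. The meiosis and sporulation list (33 genes, median 0.38, adjusted p = 0.0663) passed only without array 2 labelled RNase H1 among the fits that leave out an array (median 0.86, adjusted p = 0.0187). It also passed after median scaling (adjusted p = 0.0386), with pseudocounts of 16 (adjusted p = 0.0498) and 64 (adjusted p = 0.0491), and without an intensity trend (adjusted p = 0.0335).

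Of 17 genes of the tricarboxylic acid cycle, IDH1 and IDH2, the subunits of the NAD-dependent isocitrate dehydrogenase, were 2.88-fold higher (log2 1.53 ± 0.09) and 1.70-fold higher (0.76 ± 0.07), and 0 were lower over all genes. IDH2 was not past the threshold after median scaling (adjusted p = 0.0765). When adjusted over the list alone, 4 were higher and 7 lower, and the list did not pass (median −0.29, adjusted p = 0.215); fry pointed up. SDH1, a succinate dehydrogenase subunit, had a log2 fold change of −1.44 (adjusted p = 0.071). Of 34 nuclear genes of the respiratory chain and ATP synthase, 0 passed over all genes, with 1 higher and 18 lower at an unadjusted p under 0.05, and 1 higher and 14 lower when adjusted over the list alone. Their median was −0.49 (adjusted p = 1.61e-08 with the preset correlation, adjusted p = 0.48 with an estimated correlation), and −0.31 without array 2 labelled RNase H1. CYC1, the main cytochrome c gene, had a log2 fold change of −1.07 ± 0.15 (adjusted p = 0.0587), and COX4, a subunit of cytochrome oxidase, one of −1.02 ± 0.14 (adjusted p = 0.0531). Without array 1 labelled RNase H1, the log2 fold changes were −1.65 for SDH1, −1.11 for CYC1 and −1.10 for COX4. Without array 2 they were −1.24, −1.04 and −0.95. After quantile scaling SDH1 (adjusted p = 0.0458) and COX4 (adjusted p = 0.04999) passed, and after median scaling COX4 (adjusted p = 0.0496).

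In carbon metabolism, 3 of 17 probe sets of 15 hexose transporters were higher and 0 lower over all genes, and 3 were higher when adjusted over the list alone. These were HXT2 at 2.70-fold (log2 1.43 ± 0.16), HXT3 at 1.88-fold (0.91 ± 0.10) and HXT1 at 1.69-fold (0.75 ± 0.10). HXT7, a high-affinity transporter, had a log2 fold change of −1.76 ± 0.63 that was not past the threshold (adjusted p = 0.194). It was −2.70 without array 1 and −0.83 without array 2 labelled RNase H1. HXT1 did not pass without either control array (adjusted p between 0.217 and 0.298), nor HXT2 without control array 2 (adjusted p = 0.0807), and HXT1, HXT2 and HXT3 were not past the threshold after median scaling (adjusted p = 0.0774, 0.0595 and 0.0796). The hexose transporter list did not pass (adjusted p = 0.068), but passed without control array 2 (adjusted p = 0.00389) and without array 2 labelled RNase H1 (adjusted p = 0.0405), with no dim filter (adjusted p = 0.0438) and with a mean signal above 100 (adjusted p = 0.0283). Of 21 gluconeogenesis and glyoxylate genes, 0 passed over all genes and 0 when adjusted over the list alone, with 5 higher and 1 lower at an unadjusted p under 0.05. Their median was 0.59 (adjusted p = 0.0328 with the preset correlation, adjusted p = 0.43 with an estimated correlation), and the list did not pass when any array was left out (adjusted p between 0.0509 and 0.152, with the lowest median, 0.26, without array 1 labelled RNase H1). It did not pass either after quantile (median 0.39, adjusted p = 0.0811) or loess scaling (median 0.41, adjusted p = 0.139), or with a mean signal above 100 (median 0.30, adjusted p = 0.113), and with a pseudocount of 64 it passed at a median of 0.18. SPG4 and MOH1, genes linked to survival in stationary phase, rose 17.7-fold (4.15 ± 0.53) and 9.40-fold (3.23 ± 0.37). SPG4 was not past the threshold after quantile (adjusted p = 0.0702), median (adjusted p = 0.0595) or loess scaling (adjusted p = 0.0732), and its log2 fold change was 2.54 with a pseudocount of 64. MOH1 was at 1.60 with that pseudocount (adjusted p = 0.0615), and was not past the threshold with a mean signal above 100 (adjusted p = 0.0584).

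All 58 ribosome biogenesis genes lay above 0, with a median of 0.61 (adjusted p = 2.09e-09 with the preset correlation, adjusted p = 0.70 with an estimated correlation). Over all genes 1 was higher and 0 lower, and 6 were higher when adjusted over the list alone. That 1 was UTP10, part of the complex that processes the small subunit RNA, at 2.35-fold (log2 1.23 ± 0.14), which did not pass without either control array (adjusted p between 0.0758 and 0.111) or after median scaling (adjusted p = 0.0627). The list's median was 1.10 in array 2 labelled RNase H1 alone and 0.15 in array 1 alone, while the induced stress response list had −1.27 in array 2 and 0.47 in array 1. Of 148 probe sets of 128 ribosomal protein genes, 143 lay below 0, with a median of −0.19 (adjusted p = 9.07e-21 with the preset correlation, adjusted p = 0.43 with an estimated correlation). None of these 148 passed over all genes or when adjusted over the list alone, with 0 higher and 89 lower at an unadjusted p under 0.05. The median was −0.07 after quantile scaling and −0.03 after loess scaling. The induced stress response list of 42 genes had a median of −0.44 (adjusted p = 0.409) and passed as lower without control array 1 (median −0.62, adjusted p = 0.0266) and without array 1 labelled RNase H1 (adjusted p = 1.63e-06), but as higher without array 2 labelled RNase H1 (median 0.47, adjusted p = 0.00587).

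**Figure D3:**
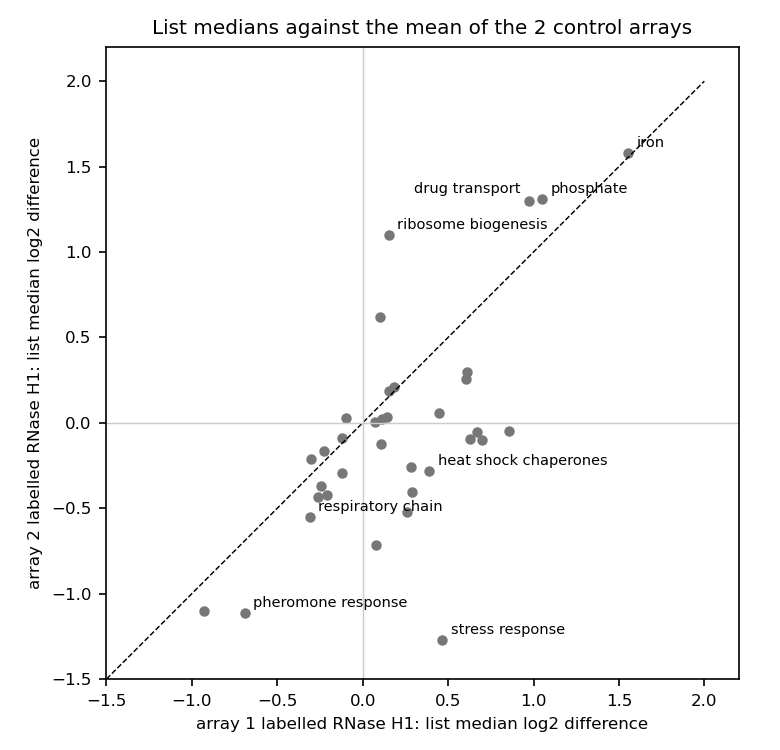
Median log2 difference of each of 35 gene lists from the mean of the control arrays, in array 1 (x axis) and array 2 (y axis) labelled RNase H1; each point is a list and the dashed line marks equal values. The iron list lies at 1.55 and 1.58, while the stress response list lies at 0.47 and −1.27.

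Of 35 Gcn4 targets in amino acid synthesis, 2 were higher and 0 lower over all genes, and 3 were higher when adjusted over the list alone. These 2 were LYS20, a homocitrate synthase of lysine synthesis, at 2.13-fold (log2 1.09 ± 0.13), and CPA1, a carbamoyl phosphate synthetase subunit of arginine synthesis, at 1.84-fold (0.88 ± 0.09). The list's median was 0.17 (adjusted p = 0.00378 with the preset correlation, adjusted p = 0.43 with an estimated correlation) and 0.27 after loess scaling. CPA1 did not pass without either control array (adjusted p between 0.0834 and 0.0931), nor LYS20 without control array 2 (adjusted p = 0.109), nor either of them after median scaling (adjusted p = 0.0614 for CPA1 and 0.0724 for LYS20). Of 24 sulphur genes under Met4, 1 was higher and 0 lower over all genes, and 4 were higher and 1 lower when adjusted over the list alone. That 1 was SUL1, a sulphate permease, which rose from a signal of 11.0 to 213 (19.2-fold, 4.26 ± 0.31), with a log2 fold change of 1.88 at a pseudocount of 64. The sulphur list had a median of 0.47 (adjusted p = 0.0387 with the preset correlation, adjusted p = 0.48 with an estimated correlation) and did not pass without array 1 labelled RNase H1 (median 0.30, adjusted p = 0.112). STP4, a zinc finger protein gene, rose 8.51-fold (3.09 ± 0.32).

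Of 25 ergosterol genes, 1 was lower and 0 higher over all genes, and 10 were lower and 1 higher when adjusted over the list alone. That 1 was ERG13, the synthase of hydroxymethylglutaryl-CoA, 1.64-fold lower (log2 −0.71 ± 0.09), which did not pass without either control array (adjusted p between 0.301 and 0.427), nor after quantile (adjusted p = 0.0528), median (adjusted p = 0.0773) or loess scaling (adjusted p = 0.0635). The ergosterol list had a median of −0.31 (adjusted p = 2.46e-04 with the preset correlation, adjusted p = 0.43 with an estimated correlation). Of 32 proteasome genes, 0 passed over all genes and 0 when adjusted over the list alone, with 0 higher and 11 lower at an unadjusted p under 0.05. Their median was −0.27 (adjusted p = 2.13e-05 with the preset correlation, adjusted p = 0.48 with an estimated correlation). Of 15 genes of the unfolded protein response, 0 passed over all genes, with 1 higher and 3 lower at an unadjusted p under 0.05 and as many when adjusted over the list alone. Their median was −0.34 (adjusted p = 0.0184 with the preset correlation, adjusted p = 0.48 with an estimated correlation), and the list did not pass without array 1 labelled RNase H1 (adjusted p = 0.0509). Outside these lists, CWP1, a mannoprotein, was 3.25-fold lower (−1.70 ± 0.15), and CSI2, a gene linked to chitin synthesis, 2.46-fold lower (−1.30 ± 0.17). CSI2 did not pass without either control array (adjusted p between 0.339 and 0.501).

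**Figure D4:**
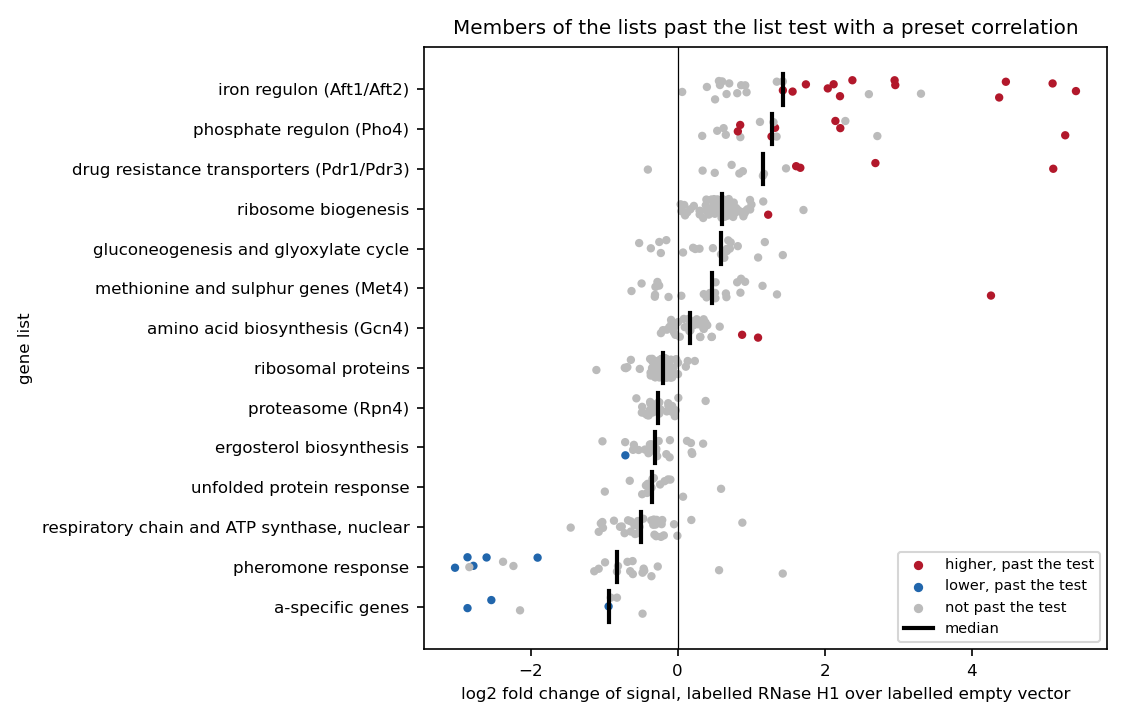
Log2 fold change of each member (x axis) of the 14 lists past the list test with the preset correlation (y axis); each point is a probe set, coloured where it passed the test over all genes, and black bars are list medians. Medians run from −0.94 for a-specific genes to 1.43 for the iron regulon.

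The 25 RNase H and R-loop factors did not move as a list: the median was 0.01, the mean −0.03, and the test pointed down (adjusted p = 0.964). In limma 0 of them passed over all genes and 0 when adjusted over the list alone, with 0 higher and 4 lower at an unadjusted p under 0.05. Subunits of RNase H2 had log2 fold changes of −0.56 ± 0.20 (RNH201, adjusted p = 0.19), 0.06 ± 0.17 (RNH202, adjusted p = 0.86) and −1.16 ± 0.30 (RNH203, adjusted p = 0.12). The plasmid marker LEU2 had signals of 12568 and 12870 in the control arrays and 10348 and 10619 in the others (log2 −0.28 ± 0.04, adjusted p = 0.0663). HIS3 had signals of 3288 and 3443 against 4098 and 3352 (0.14 ± 0.12, adjusted p = 0.52). The labels give the strain the allele his3Δ1, known as a partial deletion of HIS3, so this bright signal in all 4 arrays stands beside a marker labelled as deleted, and whether the probes lie outside the deleted part was not tested. MET17, deleted in this strain, had signals of 4.01 and 3.98 against 9.02 and 2.33, and the deleted URA3, below the dim filter, 0.325 and 0.183 against 2.92 and 4.04. Without array 1 labelled RNase H1 the log2 fold changes were −0.26 for LEU2, −0.49 for RNH201 and −1.53 for RNH203. Without array 2 they were −0.30, −0.64 and −0.80, with 0.28 for HIS3.

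In all, 14 of 35 lists passed with the preset correlation, 7 higher and 7 lower, 0 with an estimated correlation and 10 with fry. Among the 21 that did not pass with the preset correlation, 16 had 0 of 258 members past the limma test, with 28 higher and 24 lower at an unadjusted p under 0.05, and 2 higher and 5 lower when adjusted over the list alone. The 0 with an estimated correlation partly reflects the 2 degrees of freedom of that test. For drug resistance genes the estimate was −0.0263, below the preset 0.01, yet the unadjusted camera p went from 2.26e-09 to 0.0240. For ribosome biogenesis the estimate was 0.866, far above the preset. Of the copper genes, 1 of 8 rose, 1 was higher and 2 were lower when adjusted over the list alone: CUP1-1, a metallothionein whose probe set is shared with its copy CUP1-2, at 1.29-fold (log2 0.36 ± 0.04; 0.57 after loess scaling). CUP1-1 did not pass without either control array (adjusted p between 0.0807 and 0.139) or after median scaling (adjusted p = 0.126). Its signals of 15139 and 15619 were the highest on the arrays labelled RNase H1. Whether the top of the signal range limits its fold change was not tested. The copper list had a median of 0.11, a mean of −0.02 and a test that pointed down (adjusted p = 0.967). Genes with textbook non-coding or antisense transcription had 1 of 14 higher, PHO84, 0 lower, and 3 higher and 1 lower when adjusted over the list alone (median 0.13, adjusted p = 0.410). IMD2, a member of this list and of the purine list, was not past the limma threshold as reported. It passed as lower after quantile (log2 −2.47, adjusted p = 0.0227), median (−2.43, 0.0451) and loess scaling (−2.40, 0.0354), and with the replicate block (−2.40, 0.0332). The adjusted p was 0.0520 for histones, which passed without control array 2 (adjusted p = 0.0330), after median scaling (adjusted p = 0.0395), with no dim filter (adjusted p = 0.0474), and with pseudocounts of 16 (adjusted p = 0.0498) and 64 (adjusted p = 0.0491). It was 0.104 for purine synthesis, which passed without array 1 labelled RNase H1 (adjusted p = 0.0283) and after loess scaling (adjusted p = 0.0243). It was 0.115 for thiamine genes and 0.174 for seripauperins, which both passed without array 2 labelled RNase H1 (adjusted p = 0.0187 and 0.00239). Subtelomeric helicases and COS genes had 0.422 and heat shock chaperones 0.793, and both passed as lower without array 1 labelled RNase H1 (adjusted p = 0.0478 and 0.00411). Heat shock chaperones passed as higher without array 2 labelled RNase H1 (median 0.39, adjusted p = 0.00890). They had a median of −0.08 and a mean of 0.01. Glycolysis had 0.117 with a median of −0.11, but passed as higher after loess scaling (median 0.0649, adjusted p = 0.0169). DNA damage genes had 0.957 with fry pointing down from a median of 0.11, flocculins 0.957 with fry pointing down from a median of 0.20, and galactose genes 0.793 with a median of 0.08 and a mean of −0.03. Leucine genes had 0.970 with a median of 0.03 and a test that pointed down, as did the 3 strain markers with 0.663 and a median of 0.14. The lists of mitochondrially encoded genes and of Ty elements matched 0 tested probe sets by name, although YGR109W-A of Ty3, given above, was tested under its systematic name.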

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

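The tests of a single array, of amplification bias, of other mating types, of alpha cells, of G1/S genes and of growth state were chosen only after the result was seen. Of 244 unlisted probe sets with a mean signal above 8.06, the 99th percentile of S. pombe probe sets, 5 were higher and 2 lower in the arrays labelled RNase H1 in limma. They were picked out because they show a signal in data outside the comparison of genes. The 5 rises were 3.32, 1.87, 3.17, 1.99 and 0.81 on the log2 scale, and the 2 falls −2.58 and −2.49. The annotation names no gene for them. The rise of 3.32 started from a mean signal of 6.74 in the controls, below 8.06, so its size is uncertain. Above a mean signal of 8.06, 0 of 10 reporter probe sets passed in the same model, with 1 at an unadjusted p under 0.05. Of 18 S. pombe probe sets 0 passed, with 0 at that p. No group held enough samples for a test of a sample far from the others, and there was no second contrast to compare.

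The rise of the iron regulon (median 1.43) was set against 3 technical explanations. Scaling of the arrays is argued against by the lowest median under 3 other scalings, 1.40. Array medians lay between 9.13 and 9.24 on the log2 scale, so centring them could hardly have moved the iron median. Only quantile and loess scaling put it to a test. A single array is argued against by the lowest median over the 4 pairs of arrays, 1.49. Bias of amplification towards 3' ends is argued against as well, since the shift in the array with the smaller actin excess was 1.02 times that in the other. With these set aside, a response of the cells to the plasmid labelled RNase H1 may be the source, as a hypothesis found and tested on the same data; whether the insert was expressed, and whether the cultures differed in anything else, stays untested.

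The fall of mating genes was set against cells of another kind in the cultures. As the whole cause, cells of another mating type would lower each a-specific transcript alike, but BAR1 and STE2 differed by −1.60 ± 0.19 (SE) on the log2 scale. Such cells as part of the cause stay open in this test. Alpha cells are argued against by MF(ALPHA)1, their abundant pheromone transcript, with a signal of at most 13.0 in the arrays labelled RNase H1. However, the alpha-specific STE3 had 138 and 75.6 there against 33.6 and 41.5 in the controls (log2 1.45 ± 0.40, adjusted p = 0.13). Its log2 fold change was 1.02 without array 1 and 1.88 without array 2 labelled RNase H1. A smaller share of cells in G1/S stays open: the G1/S list without CLN2, CLB6 and SVS1 had a median of −0.62, but no list of another phase lay above 0, since the G2/M median was −0.42 and M/G1 genes went both ways (median −0.23, mean −0.03). A change of pheromone signalling itself was not tested and may remain.

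The wider gap between the 2 arrays labelled RNase H1 (median SD of 0.236, against 0.0756 in the controls, on the log2 scale) was set against noise and growth. Noise of dim probe sets is argued against, since in the brightest of 4 equal groups of probe sets the gap was 2.72 times that of the controls. Gain or loss of a chromosome in 1 culture is argued against, since the chromosome median farthest from 0 was −0.22. A difference in growth state is a candidate explanation: between the arrays, the induced stress response list shifted by −1.49 and the ribosome biogenesis list by 0.85. No biological explanation named by the design was tested for it.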

How the results depend on the processing

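Of the alternatives, the mean signal above 100 and the crossed block were chosen only after the result was seen. The direction of the 81 genes was largely fixed in advance. Their arrays did not overlap, so leaving out 1 array or adding a pseudocount cannot reverse a gene. Filters, the intensity trend, robust eBayes and blocks leave the fold change as it is. Only the scalings could have reversed a direction. In all settings with a fit the 81 genes, where tested, kept their direction, and for the 55 of them named here 151 of 824 values were no longer past the threshold: 48 without an intensity trend, 20 and 18 without a control array, 17 after median, 3 after quantile and 3 after loess scaling, 10 and 4 with pseudocounts of 64 and 16, 10 with robust eBayes, 9 with the replicate block and 9 with a mean signal above 100. Among values of lists 509 were on the same side, 26 kept their direction and became past the threshold, 30 ceased to be past it, and 26 reversed, 3 of them past the threshold. Genes higher and lower, 62 and 19 as reported, were 66 and 24 after quantile, 43 and 17 after median and 74 and 19 after loess scaling, 62 and 19 with either other dim filter, 59 and 14 with a pseudocount of 16, and 51 and 13 with a mean signal above 100. Lower genes were 12 with a pseudocount of 64 and 12 with robust eBayes (the cause was not tested). Without an intensity trend 7 were higher and 0 lower in limma, as each gene's variance was then drawn towards 1 common value. With an adjusted p under 0.10 there were 192 and 173, and with 1.5-fold in all 4 pairs of arrays and no test 300 and 149, by construction. Grouping each control with an array labelled RNase H1 gave at most 36 by that fold rule and 0 in limma. At an unadjusted p under 0.05 there were at most 55 in limma. These splits are too few for a share under 0.05. The difference between the labelled groups also enters the spread within each mixed group, so the counts do not estimate false calls. Leaving out 1 array gave 54 to 1184 higher and 10 to 1604 lower: without an array of the noisier pair, the lone array is assumed to vary like the controls. Camera with an estimated correlation, on 2 degrees of freedom, passed 0 lists at unchanged medians. Fry passed 10, without 5 of the 14 lists and with 1 more, that of non-coding transcription. The 5 without a pass in fry were ribosome biogenesis (adjusted p = 0.383), the proteasome (0.108) and the respiratory chain (0.0908). The others were the unfolded protein response (0.0908) and sulphur genes (0.0893). As a block, the replicate numbers gave 66 and 16, of which 54 and 13 were shared, although the deviations of same-numbered arrays correlated by −0.303. The crossed block gave 483 and 454. With the replicate block, histones passed the list test (adjusted p = 0.0452) and gluconeogenesis genes did not (adjusted p = 0.0656). PRM1, CSI2, PHO81, UTP10, HXT1, ERG13, PDR3, GAS3 and SVS1 were then not past the threshold (adjusted p between 0.0507 and 0.106).

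The reversals were of genes and lists not past the test as reported, and the cause was not tested. RNH1 was 0.00218 after loess scaling and −0.0705 to 0.0616 with 1 array left out. MET17 was −0.42 after quantile and −0.24 after loess scaling. After quantile scaling, the medians were 0.00788 for glycolysis, −0.00945 for non-coding transcription, −0.15 for markers, −0.0473 for flocculins and −0.11 for copper genes. After loess scaling they were 0.0649 for glycolysis (then past the list test, adjusted p = 0.0169), −0.10 for non-coding transcription, −0.0835 for markers, 0.0261 for heat shock chaperones and −0.0506 for copper genes. R-loop factors had −0.0199 after median centring. With 1 array left out, MET17 ran from −0.78 to 1.18, HIS3 from −0.00553 to 0.28 and MF(ALPHA)1 from −0.88 to 0.40. List medians then ran from −0.41 to 0.29 (galactose), −0.0947 to 0.18 (copper), −0.52 to 0.26 (alpha-specific), −0.0501 to 0.86 (meiosis), −0.0538 to 0.67 (hexose transporters), −0.10 to 0.63 (seripauperins), −0.26 to 0.28 (markers), −0.10 to 0.70 (flocculins), −0.12 to 0.11 (leucine), −1.27 to 0.47 (stress response, past the list test at both ends), −0.71 to 0.0782 (subtelomeric) and −0.28 to 0.39 (heat shock, past it at both ends). Of the lists with called members, iron genes past the threshold ranged from 4 without an intensity trend to 26. Signals near those of S. pombe probe sets, such as MET17 at 2.33 to 9.02, limit what can be read from dim genes.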

Other observations

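The lists in this part, and all tests in it except that of a chromosome for the 81 genes, were chosen only after the result was seen, and so were the genes named only here. All 28 tested targets of the G1/S activators SBF and MBF lay below 0, with a median of −0.66, and 2 fell over all genes in limma: CLN2 and SVS1, a cell wall protein, which was 1.99-fold lower (log2 −0.99 ± 0.12) and did not pass without either control array (adjusted p between 0.217 and 0.249) or after median scaling (adjusted p = 0.0673). Adjusted over the list alone, 11 G1/S genes were lower (adjusted p = 3.45e-10 with the preset correlation, adjusted p = 0.38 with an estimated correlation). The 11 tested G2/M genes all lay below 0 (median −0.42, adjusted p = 0.00347 with the preset correlation, adjusted p = 0.61 with an estimated correlation). In limma 0 of these 11 passed over all genes or when adjusted over the list alone, with 3 lower at an unadjusted p under 0.05, and the gap between the 2 arrays labelled RNase H1 was −0.51. The 14 daughter-cell and M/G1 genes went both ways (median −0.23, mean −0.03, adjusted p = 0.494), and 1 rose: DSE2, a glucanase of cell separation, by 1.72-fold (0.78 ± 0.09), not past the threshold without control array 2 (adjusted p = 0.121) or after median scaling (adjusted p = 0.0765).

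Of 55 genes of the mitochondrial ribosome, 53 lay above 0, with a median of 0.33 (adjusted p = 5.69e-09 with the preset correlation, adjusted p = 0.35 with an estimated correlation). In limma 0 passed over all genes or when adjusted over the list alone, with 16 higher at an unadjusted p under 0.05. Of 21 genes of iron-sulphur cluster assembly and haem synthesis, ISA1, an assembly factor, was 2.55-fold higher (log2 1.35 ± 0.15) and HEM15 lower, while the median was 0.01 (adjusted p = 0.742). ISA1 did not pass without either control array (adjusted p between 0.0906 and 0.112) or after median scaling (adjusted p = 0.0556). In the cell wall list of 26 (median −0.16, mean 0.05, adjusted p = 0.154), the stress-induced glucan synthase gene GSC2 was 5.99-fold higher (2.58 ± 0.22), and CWP1 and the glucan-modifying gene GAS3 were lower, GAS3 by 1.97-fold (−0.98 ± 0.12), which did not pass without either control array (adjusted p between 0.258 and 0.272) or after quantile (adjusted p = 0.0588) or loess scaling (adjusted p = 0.0581). The 15 glycogen and trehalose genes had a median of −0.75 (adjusted p = 0.0351 with the preset correlation, adjusted p = 0.67 with an estimated correlation) and a gap of −1.76 between the 2 arrays labelled RNase H1, with 0 past the limma test and 2 lower at an unadjusted p under 0.05. Most of these genes also stand in the induced stress response list, which did not pass (camera adjusted p = 0.409), so they are no separate finding. Of the 81 genes, 5 neighbouring pairs moved the same way, against 0.621 on average in 100000 random sets (permutation p = 3.4e-04): SUL1 with PCA1, PCA1 with PHO89, FIT2 with FIT3, SNO1 with SNZ1 of vitamin B6 synthesis, and YAR068W with PHO11. YAR068W did not pass without either control array (adjusted p between 0.0834 and 0.0842), nor SNZ1 after median scaling (adjusted p = 0.0672).

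The 3 neighbours on chromosome II might have risen through gain of a chromosome segment. As the whole cause this is argued against by PHO89 and PCA1, a cadmium transporter gene between PHO89 and SUL1. PHO89 rose further than PCA1 by 3.23 ± 0.37 (SE) on the log2 scale. Of the 10 nearest other genes, 0 passed in limma (median 0.34, 1 at an unadjusted p under 0.05). Those beyond PHO89 ran from 0.03 to 1.42 and those before SUL1 from −0.40 to 0.39. A gain that runs past PHO89, as part of the cause, stays open. PCA1, 4.11-fold higher (2.04 ± 0.19), did not pass without control array 1 (adjusted p = 0.0758). Gain or loss of a chromosome does not account for the 81 genes, since the chromosome median farthest from 0 was −0.0726. Signalling from dysfunctional mitochondria could accompany the lower respiratory genes: the 6 retrograde targets other than IDH1 and IDH2 all lay above 0, with a median of 0.36, but their camera p was 0.00264 with the preset correlation and 0.0911 with an estimated one, which leaves it open. Of these 6, ACO1 and CIT2 also stood in the tricarboxylic acid cycle list tested before, so the 6 were not all unseen. The whole list of 8 had a median of 0.52, with 2 higher over all genes and 6 when adjusted over the list alone (adjusted p = 3.73e-05 with the preset correlation, adjusted p = 0.35 with an estimated correlation).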
